A study of Mus musculus with 2 samples.

How the data were processed

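The series measured RNA in single medullary thymic epithelial cells (mTECs), the cells of the thymus that display antigens of other tissues to developing T cells. Female C57BL/6J mice aged 4 weeks received 7 daily intraperitoneal injections of spermidine at 15 mg/kg in phosphate-buffered saline (PBS), or of PBS alone, per the labels. Cells with CD45 were depleted on beads, mTEChi cells (which hold the Aire-expressing stage) and post-Aire mTEClo cells were sorted by flow cytometry, per the labels' protocols. The 4 samples, 2 per treatment, were tagged with antibody-coupled hashtags and pooled into 1 run of the droplet-based 10x Genomics 3' v3 chemistry, per the labels' protocols. Hashtags HT4 and HT5 stood for PBS replicates 1 and 2, and HT2 and HT3 for spermidine replicates 1 and 2, per the labels. The labels did not say that the replicates came from separate mice, so p-values measure only the spread between these hashed samples, which may be technical. The mixing ratio of the sorted populations was not given in the sources used here, and sorting and pooling can set the shares of cell classes.

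The deposited values were raw counts of unique molecular identifiers (UMIs) per gene or hashtag and barcode, made by the authors with Cell Ranger 7.1.0, per the file headers. The genome build mm10, bcl2fastq and Seurat were named in the submitters' processing notes, and the annotation, the cell filter and the read filters were not given in the sources used here. The counts covered 55487 genes and 15 hashtags in 12139 barcodes, with 158263030 gene UMIs in all, at least 501 and a median of 9607 per barcode. Hashtag counts stayed out of library sizes and tests. Of the gene identifiers, 54435 had the same identifier and version in the GENCODE M21 annotation (GRCm38, the same assembly as mm10), 55227 had the same identifier in any version, and positions of named genes were taken from it. A 3' count of a gene with a near-identical copy (Ccl21a, Dcpp3, Hamp, Ifi27l2a and Ifi27l2b, Klk1b26, Trbc1, many ribosomal protein genes) is uncertain, since the treatment of reads that match several genes was not given in the sources used here.

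Barcodes were assigned to the 4 hashed samples from their hashtag counts with HTODemux of Seurat 5.3.0 (centred log ratio, positive quantile 0.99), and barcodes called doublets or negatives were left out. Cells with at least 1000 UMIs, at least 500 genes and under 15% mitochondrial UMIs were kept. Each limit alone excluded 589, 1712 and 3078 barcodes, and 8534 passed all of them. Of these, 4709 were assigned to 1 sample, 1027 were hashtag doublets and 2798 were negatives. Under an assignment with 6 hashtags, added later, 2299 of the negatives carried HT6 or HT7, which have no sample in the labels. In it 897 of the 4709 assigned cells were doublets. No caller of doublets from RNA was used: Scrublet marked 0 of the 8534 cells, which was taken as a failure of the caller, so the alternative with it was not run. The kept cells were clustered together in scanpy 1.11.5, without sample or treatment: counts per 10000, log transform, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1. The 16 clusters were named from 21 marker lists, which gave 13 classes, called "like" since they rest on markers, and each cluster had at least 8 detected members of its list. Members of the list stood among the 10 leading genes of 11 clusters. The 5 Aire-stage and tuft-like clusters had none there, and were named from 7 to 12 list members that were more than 2-fold higher than in the other cells. Cluster 8, named goblet- or secretory-like for 2 leading genes, also had 9 of 12 keratinocyte markers more than 2-fold higher. Clusters 2 and 4 formed the Aire-stage class and clusters 0, 1 and 7 the tuft-like class. The keratinocyte-, tuft-, microfold-, neuroendocrine-, ciliated-, muscle-, enterocyte- or hepatocyte- and goblet- or secretory-like classes formed the post-Aire mimetic class, mTECs that resemble cells of other organs.

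Counts were summed per hashed sample and class, since cells are not replicates, and 2 sums per treatment were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the default filter of low counts (filterByExpr, minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment at 0.05. CPM, the counts of a gene scaled to a common library total, used TMM-scaled library sizes computed from the deposited counts. Single classes were fitted where each sample had at least 20 cells. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it, and adjusted over the 14 lists and, separately, over the marker lists of 7 other cell types. The 14 lists were Aire-dependent tissue antigens, antigen presentation and co-stimulation, Aire and partners, polyamine metabolism and transport, interferon-stimulated genes, Z-nucleic acid sensors with inflammasome or necroptosis genes, NF-kB targets, NFE2 and MAF factors, autophagy and lysosome, cell cycle, immediate early and heat shock, oxidative phosphorylation, cytosolic translation, and DNA damage and p53 targets. The 7 marker lists were those of cortical thymic epithelial cells (cTECs), thymocytes, B cells, myeloid, fibroblast, endothelial and erythroid cells. Sparse genes of the Aire stage were those with a UMI in 0.2 to 5% of Aire-stage cells and at least 2 times the CPM of transit-amplifying-like cells, with the 4 samples weighted equally. Rare genes per cell were counted, after thinning each cell to 5000 UMIs and leaving out shallower cells, among genes with a UMI in under 2% of Aire-stage cells. Shares of classes and genes per cell were compared with two-sided exact permutation tests over the 4 samples, whose smallest possible p is 0.333.

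The lists, markers, tests and the rule for named genes were fixed before the data were examined. The rule named up to 10 genes with the smallest p per direction and comparison among those past the threshold without overlap between groups, or else 5 per direction that did not pass, the 4 members of each list with the smallest p in Aire-stage cells, and 16 genes chosen in advance. Gene models without a name were left out of the first part. Genes called in a single mimetic class were named in full.

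The alternatives fixed in advance were DESeq2 1.42.0 with its own size factors, library size without TMM, genes with 1 or more counts in place of the filter, each sample left out in turn, the replicate number as a block, a margin rule for hashtags (highest count at least 10 and at least 3 times the next), cells with 3000 or more UMIs, Leiden resolution 0.5, thinning of samples to the lowest total, thinning of cells to 3000 or 10000 UMIs, and other definitions of the sparse genes. Leaving out a sample left 1 against 2, so the lone sample was assumed to vary like the other group, and gained or lost calls in these fits rest on that. Added after the data were examined were an assignment with the 6 hashtags that held more than 1% of hashtag UMIs each, the same with an estimated correlation for lists, a limit on the count of a gene in a cell at 5 or at the 99th percentile of the class (capped counts), separate fits of clusters 2 and 4 for genes, sparse genes and rare genes, all cells without thymocyte-like and myeloid-like clusters, and fits of the immature mTEC-like class. The test of CA repeats at promoters was not run because a genome sequence was not used here.

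The scripts were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. In the simulation of Aire-stage cells, over 18817 genes, edgeR recovered 15% of genes changed 2-fold and 55% of those changed 4-fold with 9 false calls, and DESeq2 26% and 66% with 30 false calls. In that of transit-amplifying-like cells, over 12293 genes, edgeR recovered 51% and 87% with 10 false calls. Over 17708 genes of post-Aire mimetic cells the shares were 53% and 84% with 17 false calls, over 22660 genes of all cells 51% and 66% with 16, and over 14047 genes of tuft-like cells 69% and 93% with 15. A list of 40 genes shifted by 0.5 on the log2 scale was found in each simulation, and 2, 0, 0, 0 and 0 of 50 unshifted lists had p under 0.05 (camera) in the same order. Genes were drawn independently and lists at random. These lists therefore could not show how often the preset correlation passes unshifted lists of co-expressed genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.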

Results

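The study asked how spermidine, a polyamine that can favour unusual DNA forms such as Z-DNA, changes RNA levels in mTECs, in which Aire switches on genes of other organs. RNA was counted in single cells of 4 hashed samples. PBS replicate 1 held 1335 kept cells with 23172408 UMIs and a median of 15736 per cell, and PBS replicate 2 held 993 cells with 17668782 UMIs and a median of 16378. Spermidine replicate 1 held 1374 cells with 25673749 UMIs and a median of 17365, and spermidine replicate 2 held 1007 cells with 18230040 UMIs and a median of 16782. Error values are SD over n = 2 samples per group unless given as a standard error (SE) of a fitted log2 fold change, and log2 fold changes are of spermidine over PBS. Chance alone separates both spermidine from both PBS values for 33.3% of genes.

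Aire-stage and dividing cells made up more of the spermidine samples, and tuft-like and immature cells less. The Aire-stage share was 24.7% ± 5.8 (SD, n = 2) with PBS and 35.3% ± 0.327 (SD, n = 2) with spermidine. The share of transit-amplifying-like cells, the dividing precursors led by Ube2c, Ccna2 and Mki67, was 6.71% ± 0.908 (SD, n = 2) with PBS and 12.3% ± 0.375 (SD, n = 2) with spermidine. Tuft-like cells, which resemble the chemosensory cells of gut and airway, made up 31.3% ± 4.25 (SD, n = 2) with PBS and 22.7% ± 0.88 (SD, n = 2) with spermidine. Immature mTEC-like cells, which express Ccl21a, were at 8.72% ± 0.778 (SD, n = 2) and 5.43% ± 0.887 (SD, n = 2). None of these differences can reach p below 0.333 in the exact permutation test, and each of these 4 had exact p = 0.333. Keratinocyte-like cells went from 3.17% to 1.81%, neuroendocrine-like cells from 6.48% to 4.36% and goblet- or secretory-like cells from 4.81% to 3.75%. Values for microfold-like cells were 5.24% and 4.30%, for ciliated-like cells 1.28% and 0.748% and for muscle-like cells 1.12% and 0.698%. The enterocyte- or hepatocyte-like share was 3.44% with PBS and 3.35% with spermidine. In the depleted and sorted pool thymocyte-like cells were still 1.53% ± 0.594 (SD, n = 2) with PBS and 3.39% ± 0.153 (SD, n = 2) with spermidine, and myeloid-like cells 1.52% and 1.87%. Within the post-Aire mimetic classes the tuft-like share was 55.0% ± 0.673 (SD, n = 2) with PBS and 54.4% ± 0.326 (SD, n = 2) with spermidine. The sum of these classes was 56.8% ± 7.03 (SD, n = 2) and 41.7% ± 1.37 (SD, n = 2) of cells. At Leiden resolution 0.5 the Aire-stage share was 10.9% with PBS and 20.3% with spermidine, beside an unnamed cluster of 23.3% and 24.1% led by Klk1b26 and Klk1b11. The Aire-stage difference of 10.6 percentage points was 6.48 without PBS replicate 1, the tuft-like difference of -8.64 was -5.63 without it, and the neuroendocrine-like difference of -2.11 was -0.573 without it and -3.65 without PBS replicate 2. Smaller classes also moved with single samples. The ciliated-like difference of -0.529 was -0.158 without PBS replicate 1 and -0.900 without PBS replicate 2, and the goblet- or secretory-like one of -1.065 was -0.484 and -1.65. The microfold-like one of -0.941 was -1.54 and -0.342 without these and -0.512 without spermidine replicate 2. Myeloid-like cells went from 0.353 to 0.767 without spermidine replicate 1 and to -0.062 without replicate 2, and enterocyte- or hepatocyte-like cells from -0.089 to 0.637 and -0.815.

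**Figure D1:**
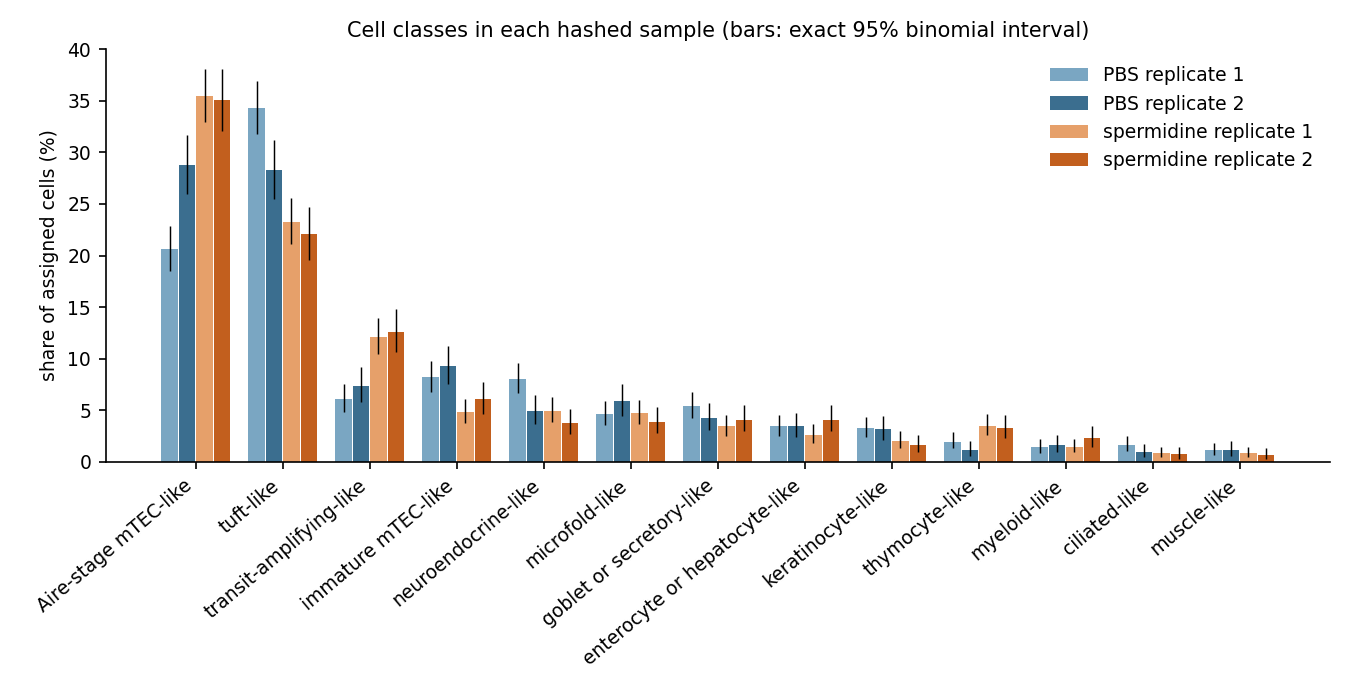
The share of each cell class among kept cells is plotted in percent for the 4 hashed samples, with 1 bar per sample and its exact 95% binomial interval. Aire-stage cells averaged 24.7% with PBS and 35.3% with spermidine, and tuft-like cells 31.3% and 22.7%.

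Within Aire-stage cells no single gene passed the threshold, and Aire itself was nearly level. The class held cluster 2, led by the calcium-binding genes S100a8 and S100a9, and cluster 4, led by the kallikrein genes Klk1b11 and Klk1b26. They were summed over 275 and 286 cells with PBS and 488 and 353 cells with spermidine, or 5300554 to 10697754 UMIs per sample. Cluster 2 was 41.0% ± 1.14 (SD, n = 2) of the class with PBS and 52.1% ± 4.32 (SD, n = 2) with spermidine. Cluster 4 held 160 of 1335 and 171 of 993 kept cells with PBS, and 219 of 1374 and 180 of 1007 with spermidine. Its share of all kept cells overlapped between the groups. That of cluster 2, with 115, 115, 269 and 173 cells in the same order, did not. Aire (ENSMUSG00000000731.15, GRCm38 chromosome 10, 78030022 to 78043610) was at 695 ± 40.2 CPM (SD, n = 2) with PBS and 759 ± 35.6 CPM (SD, n = 2) with spermidine. edgeR called 0 of 18817 genes, with 1309 genes at an unadjusted p under 0.05, while DESeq2 called 94. Without the low-count filter edgeR called 160, and without PBS replicate 1 it called 1. Fitted separately, cluster 2 gave 0 calls of 16683 genes with 926 at an unadjusted p under 0.05, and cluster 4 gave 0 of 14410 with 771, by edgeR.

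The 5 named genes with the smallest p on each side in Aire-stage cells had adjusted p of 0.250 or more in edgeR. On the higher side Krt71, a keratin of the hair follicle (GRCm38 chromosome 15, 101733949 to 101743109), had a log2 fold change of 2.06 (SE 0.133), Chgb, a granin of secretory vesicles, 2.93, Grin2a, a glutamate receptor subunit, 3.17, and the interferon-induced genes Rsad2 2.11 and Ifi27l2b 2.01. On the lower side the chemokine Ccl22 had -1.09 (SE 0.082), Hamp, the iron hormone hepcidin, -0.67, Tspan1 -1.01, the semaphorin receptor Nrp2 -0.72 and Fabp9, a fatty acid binding protein of testis, -0.68. In spermidine replicate 2 the top cell for each gene held 86.1% of the Chgb UMIs, 71.4% of those of Grin2a and 66.4% of those of Rsad2, against 34.4% for Krt71, and 66.7% of those of Ifi27l2b in PBS replicate 2. With counts capped in each cell Krt71 passed, at 1.39 (SE 0.134, adjusted p = 0.0371 in edgeR). Of the genes chosen in advance, Fezf2 was at -0.05, Cd80 at 0.04, H2-Aa at -0.08, Ins2 at 0.17, Ccl21a at -0.34 and Mki67 at 0.26. Zbp1, a sensor of Z-form nucleic acids, was at -0.12 and Adar, an editor of double-stranded RNA, at -0.07. Adjusted p ran from 0.872 to 0.986 for these 8 genes (edgeR). The leukocyte gene Ptprc was at 0.63 (adjusted p = 0.799 in edgeR).

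Among the 14 gene lists, those of the cell cycle and of cytosolic translation rose and that of antigen presentation fell in Aire-stage cells by camera with a preset correlation, and none of the 3 held with an estimated one. Cluster 2 was also a larger part of the Aire-stage class with spermidine (52.1% against 41.0%). Transit-amplifying markers, many of them in the cell cycle list, were lower in cluster 4 (mean log2 fold -2.191 against all other cells) than in cluster 2 (-0.412). The lists were not fitted within the clusters, so a changed mix of clusters cannot be told apart from a change within cells. Of 28 cell cycle genes 24 were higher, with a median log2 fold change of 0.48 and adjusted p = 3.54e-04 (camera), among them the mitotic genes Ube2c at 1.32, Aurkb at 1.54 and Birc5 at 0.79 and the chromatin gene Hmgb2 at 0.47. The top cell held 62.7% of the Ube2c UMIs of PBS replicate 2, and with capped counts Ube2c was at 0.50. All 25 translation genes were higher, by a median of 0.19 (adjusted p = 3.54e-04, camera), such as Rpl32 at 0.26, Rps2 at 0.31, Rps6 at 0.28 and Rps18 at 0.26. Of 23 antigen presentation genes 18 were lower, with a median of -0.11 (adjusted p = 0.0266, camera), such as the class I gene H2-K1 at -0.26, the co-stimulator Cd86 at -0.52, the proteasome subunit Psmb8 at -0.23 and the peptide transporter Tap2 at -0.22. With an estimated correlation the adjusted p was 0.669 for cell cycle, 0.725 for translation and 0.688 for antigen presentation. In each of these 3 lists 0 members passed in edgeR over all genes tested and 0 when adjusted over the list alone, with 5, 7 and 3 members at an unadjusted p under 0.05. Without PBS replicate 1 the adjusted p was 0.163 for cell cycle, 0.179 for translation and 0.185 for antigen presentation, and without spermidine replicate 1 it was 0.214, 0.260 and 0.409. Antigen presentation also failed without PBS replicate 2 (0.0991), without the low-count filter (0.0750), with the margin rule (0.0564) and with the replicate block (0.0809).

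Erythroid markers were higher in Aire-stage cells of spermidine samples in 5 of 5 genes, by a median of 1.56 (adjusted p = 0.0361, camera, and adjusted p = 0.648 with an estimated correlation), with 2 genes adjusted over the list alone and 0 over all genes. Thymocyte markers were higher in 8 of 9, by a median of 0.63 (adjusted p = 0.0501, camera). The erythroid call was lost without PBS replicate 2 (adjusted p = 0.279), without spermidine replicate 2 (0.112), with the margin rule (0.0565) and with capped counts (0.0574), and thymocyte markers passed without PBS replicate 1 (0.0264) and without spermidine replicate 2 (0.00375). Markers of cTECs, B cells, myeloid, fibroblast and endothelial cells had medians of -0.02, -0.11, 0.10, 0.27 and -0.11 and adjusted p = 0.893 each (camera). The means of the cTEC and the endothelial markers were 0.07 each, on the other side of 0 from their medians, with camera directions up and down.

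The lists nearest to the study's question did not pass in Aire-stage cells. Of 44 Aire-dependent tissue antigens 27 were higher and 17 lower (median 0.20, adjusted p = 0.182, camera), with 0 called by edgeR over all genes and 6 adjusted over the list alone. These went both ways: the casein gene Csn1s2a was at 1.18 (SE 0.165), while Fabp9 was at -0.68, the serpin Serpinb2 at -0.95 (SE 0.149) and the airway gene Bpifa1 at -0.73 (SE 0.131). The top cell held 60.4% of the Csn1s2a UMIs of PBS replicate 1 and 56.4% of those of Bpifa1 of PBS replicate 2, and with capped counts these genes were at 1.08 and -0.23. Of 27 genes of Aire and partners 16 were higher (median 0.05, adjusted p = 0.194), with Hipk2 at 0.38, Pdia6 at 0.27, Parp1 at 0.40 and Sirt1 at 0.18. Of 25 polyamine genes 12 were higher (median -0.04, mean 0.02, camera direction down, adjusted p = 0.950). Among these the synthesis genes Odc1, Srm, Sms and Amd1 were at -0.10, 0.31, 0.36 and 0.20, the acetyltransferase Sat1 at -0.15, the spermidine-modified factor Eif5a at 0.21, the hypusine enzyme Dohh at -0.33, Azin2 at -0.29 and Oaz3 at 1.39 (SE 0.519). Of 13 Z-nucleic acid sensor and cell death genes 4 were higher (median -0.07, adjusted p = 0.907), with Il1b at 1.19, Pycard at -0.26, Nlrp3 at -0.70 and Casp8 at 0.16. With capped counts Il1b was at 0.72. Each of these last 3 lists had 0 calls by edgeR over all genes and 0 adjusted over the list alone, with 3, 3 and 2 members at an unadjusted p under 0.05.

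Of 40 interferon-stimulated genes 21 were higher in Aire-stage cells (median 0.01, mean 0.19, adjusted p = 0.145, camera), with Isg15 at 0.44, Trim30a at 0.60 and Ifit3 at 0.90, and 1 gene, Rsad2, passed adjusted over the list alone. Immediate early and heat shock genes were higher in 19 of 25 (median 0.15, adjusted p = 0.145), with Hsp90aa1 at 0.38, Hspd1 at 0.39, Ier3 at 0.69 and Hspa1b at 0.26. Under the 6-hashtag assignment both lists passed, at adjusted p = 3.44e-04 and 0.0214 (camera), and with an estimated correlation their adjusted p was 0.578 and 0.590. Autophagy genes were lower in 20 of 29 (median -0.07, adjusted p = 0.176), with Lamp1 at -0.23 and Atg7 at -0.34, and oxidative phosphorylation genes in 21 of 26 (median -0.06, adjusted p = 0.182), with Sdha at -0.28 and Ndufv1 at -0.23. NF-kB targets had a median of 0.04, a mean of -0.03, camera direction down and adjusted p = 0.928, with Ccl20 at -0.67 and Cxcl16 at -0.28. NFE2 and MAF factors had a median of -0.02, a mean of 0.01, camera direction up and adjusted p = 0.928, with Nfe2l3 at 0.22. DNA damage and p53 targets had a median of 0.01, a mean of -0.03, camera direction down and adjusted p = 0.928, with Gadd45b at 0.27 and Btg2 at -0.38. Each of these 7 lists had 0 calls by edgeR over all genes, and each but the interferon-stimulated genes had 0 adjusted over the list alone, with 5, 5, 2, 0, 1, 0 and 2 members at an unadjusted p under 0.05 in the order given.

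**Figure D2:**
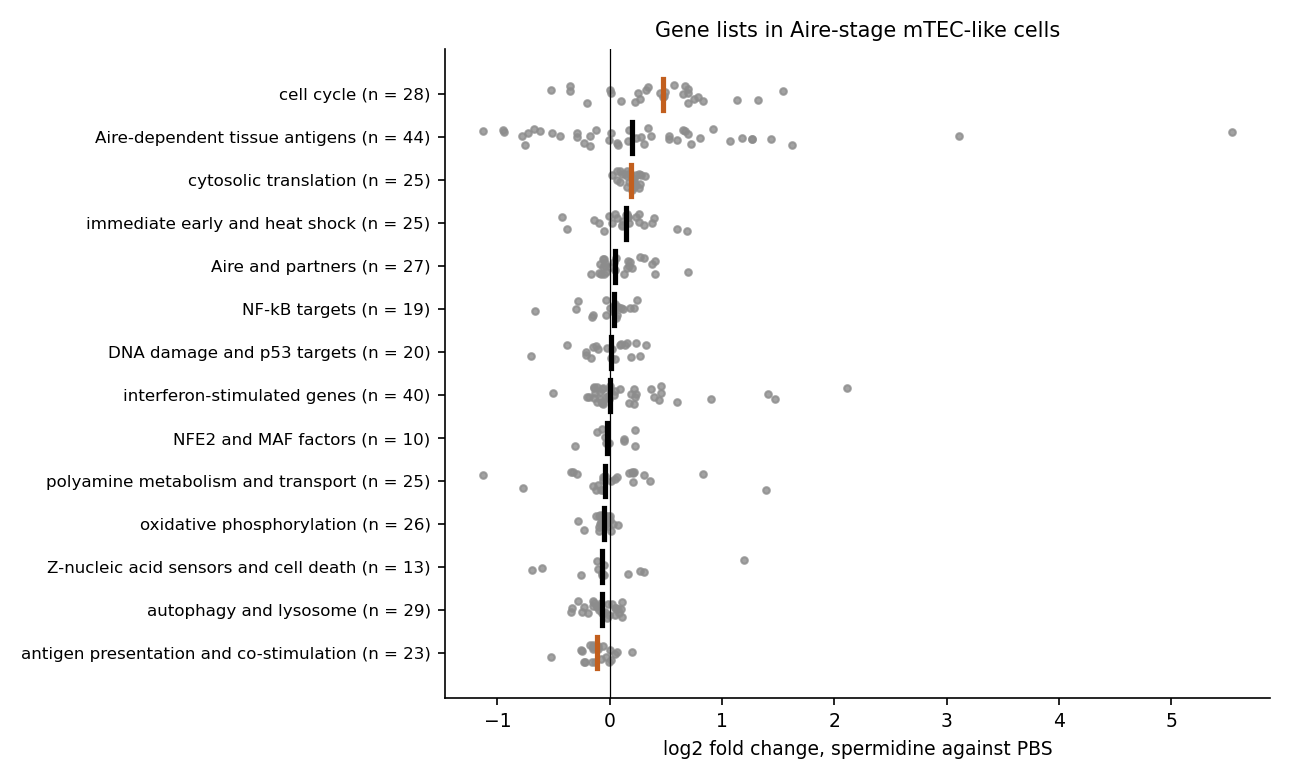
The log2 fold change of spermidine over PBS in Aire-stage cells is plotted for each member (grey points) and as the median (bar) of the 14 lists, orange where camera with a preset correlation gave adjusted p under 0.05. Cell cycle, translation and antigen presentation are orange, with medians of 0.48, 0.19 and -0.11.

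Sparsely expressed genes of the Aire stage, a stand-in for tissue antigens chosen without treatment, rose on balance by a small amount in the class as a whole, and passed in neither of its 2 clusters alone. Of 9484 such genes 3387 were testable, 1907 higher and 1480 lower, with a median log2 fold change of 0.15 over members with an SD of 1.17 (p = 0.0284, camera, and p = 0.0372 with an estimated correlation). edgeR called 0 of them, with 308 higher and 136 lower at an unadjusted p under 0.05. Their share of the class's UMIs was 1.69% and 1.77% in the PBS samples and 1.97% and 1.95% in the spermidine samples. Cluster 2, which held more rare genes per cell than cluster 4, was also a larger part of the class with spermidine (52.1% against 41.0%). Within the clusters the call was lost, with a median of 0.05 over 2398 genes in cluster 2 (p = 0.138, camera, and p = 0.0759 with an estimated correlation) and of -0.03 over 753 genes in cluster 4 (p = 0.736 and 0.742). The call was also lost with the margin rule, with the 6-hashtag assignment and without the low-count filter. In this order the camera p was 0.0555, 0.118 and 0.516. The spermidine sums held 488 and 353 cells, against 275 and 286 with PBS, and cell numbers were not equalised. What this imbalance adds to the median was not tested. Leaving out a PBS sample raised the median, and leaving out a spermidine sample lowered it. The median was 0.30 without the first PBS sample, 0.34 without the second, -0.04 without the first spermidine sample and 0.03 without the second. The camera p for these was 0.0861, 0.0377, 0.104 and 0.0103, in fits of 1 sample against 2 whose spread came from the group of 2 alone.

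Aire-stage cells held more rare genes on average in both spermidine samples, but not more genes in all. At 5000 UMIs a cell held 30.2 ± 0.412 rare genes (SD, n = 2) with PBS and 34.7 ± 2.18 (SD, n = 2) with spermidine, higher in both spermidine samples, with exact p = 0.333, the smallest the test allows. Without thinning the values were 87.3 and 102, and the difference of 4.45 was 2.90 without spermidine replicate 1 and 2.81 with the margin rule. Total genes per cell at 5000 UMIs were 2198 ± 16.5 (SD, n = 2) and 2192 ± 9.15 (SD, n = 2), exact p = 0.667, and 4530 and 4752 without thinning. In cluster 2 rare genes were 43.0 ± 0.786 (SD, n = 2) and 45.3 ± 2.13 (SD, n = 2), and in cluster 4 20.5 ± 0.252 (SD, n = 2) and 21.5 ± 0.631 (SD, n = 2). The difference was thus 2.31 (SE 1.60) and 0.987 (SE 0.481) within the clusters.

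**Figure D3:**
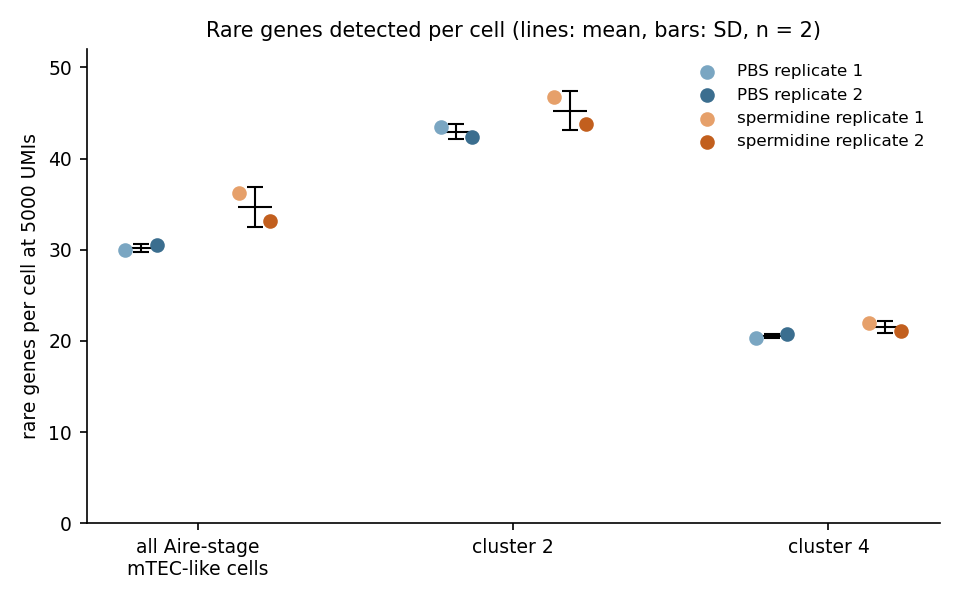
Rare genes per Aire-stage cell at 5000 UMIs are plotted for the 4 hashed samples, for the whole class and for clusters 2 and 4, with 1 point per sample. Group means were 30.2 and 34.7 in the class, 43.0 and 45.3 in cluster 2 and 20.5 and 21.5 in cluster 4.

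In transit-amplifying-like cells no gene passed, and the cell cycle list did not pass either. The class was summed over 81, 73, 166 and 127 cells of PBS replicates 1 and 2 and spermidine replicates 1 and 2. The lower genes with the smallest p were Kpna2, a nuclear import factor, at -1.33 (SE 0.172), the mitotic checkpoint gene Bub3 at -0.69 (SE 0.11), and the mitotic kinase Cdk1 at -0.82 (SE 0.135). Beside these stood Trbc1, with 22 and 15 counts with PBS and 4 and 2 with spermidine, and Ror2, with 14 and 42 counts with PBS and 1 and 0 with spermidine. The higher ones were Cdh13 at 2.5, Nefh at 3.69, Zfp382, with 2 and 3 counts with PBS and 168 and 61 with spermidine, Naa25 at 0.82 (SE 0.109) and Rps6kc1 at 1.22, all 10 with adjusted p of 0.19 or more in edgeR. The top cell for each gene held 96.7% of the Zfp382 and 89.7% of the Nefh UMIs of spermidine replicate 2, and 97.6% of the Ror2 and 93.3% of the Trbc1 UMIs of PBS replicate 2, and Cdh13 was at -0.37 under the 6-hashtag assignment. Of 28 cell cycle genes 19 were lower (median -0.23, adjusted p = 0.293, camera), with 0 called over all genes and 6 adjusted over the list alone. Immediate early and heat shock genes rose, with 16 of 23 higher by a median of 0.14 (adjusted p = 0.0267, camera, and adjusted p = 0.999 with an estimated correlation), 0 called over all genes and 4 adjusted over the list alone. Aire was at 0.00 and Fezf2 at -0.01. edgeR called 0 of 12293 genes, with 784 at an unadjusted p under 0.05, and DESeq2 called 17. Without the low-count filter edgeR called 478, and it called 1 gene without PBS replicate 2, 63 without spermidine replicate 1 and 18 without spermidine replicate 2.

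In post-Aire mimetic-like cells as 1 class, Ttr fell and no other gene passed. Ttr, the thyroxine carrier transthyretin made by liver and choroid plexus (GRCm38 chromosome 18, 20665280 to 20674321), was at 121 and 146 CPM with PBS and 19.8 CPM in both spermidine samples. Its log2 fold change was -2.75 (SE 0.118, adjusted p = 0.00599 in edgeR, lower in 2 of 2 samples). This fall rested on few cells. The top cell held 42.4% of the Ttr UMIs of PBS replicate 1 and 69.6% of those of PBS replicate 2, and with capped counts the value was 0.03 (adjusted p = 0.985) and under the 6-hashtag assignment -2.54 (adjusted p = 0.493). Genes that did not pass were, on the lower side, the keratin Krt10 at -0.60 (SE 0.06), the carbonic anhydrase Car2 at -0.75, Cdh18 at -1.23 and S100a8 at -0.93. On the higher side were the islet hormone Iapp at 0.84 (SE 0.087), Dcpp3 at 3.37, the neuropeptide Npy at 3.62, Cntn4 at 0.80 and the cytokine Il1f6 at 0.68. The top cell for each gene held 92.5% and 93.5% of the Npy UMIs in the spermidine samples, and 91.8% and 81.8% of those of Dcpp3. The cell cycle list rose, with 24 of 28 genes higher by a median of 0.30 (adjusted p = 5.12e-05, camera, and adjusted p = 0.741 with an estimated correlation), 0 called over all genes and 0 adjusted over the list alone. edgeR called 1 of 17708 genes, with 1247 at an unadjusted p under 0.05, DESeq2 29, and edgeR without the low-count filter 709, with the margin rule 0 and at Leiden resolution 0.5 0. Leaving out PBS replicate 1, PBS replicate 2, spermidine replicate 1 or spermidine replicate 2 gave 17, 4, 43 and 7 calls.

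Tuft-like cells, the largest mimetic class with 458, 281, 320 and 222 cells, held 9 genes that rose and none that fell at the threshold in edgeR. The chemokines Cxcl10 and Cxcl9, ligands of the chemokine receptor Cxcr3, lie side by side (GRCm38 chromosome 5, 92346638 to 92348889 and 92321347 to 92328079). Cxcl10 went from 22.1 ± 0.123 CPM (SD, n = 2) to 85.1 ± 10.2 CPM (SD, n = 2). Its log2 fold change was 1.94 (SE 0.118, adjusted p = 5.16e-04), and that of Cxcl9 2.34 (SE 0.181, adjusted p = 0.00203), higher in 2 of 2 samples. The other 7 were Cacna2d1, a calcium channel subunit, at 1.53 (SE 0.163), Stk33, a kinase, at 0.73 (SE 0.085), Megf11 at 0.74 and Syt1, the calcium sensor of vesicle release (GRCm38 chromosome 10, 108497650 to 109010982), at 0.48 (SE 0.064). The unnamed models E330032C10Rik, Gm6999 and Gm47782 were at 0.91, 0.75 and 1.10, and adjusted p ran from 0.0176 to 0.0468 over the 7 (edgeR). Cacna2d1 was also among the 10 leading genes of the neuroendocrine-like cluster. The top cell for each gene held 88.7% of the Cxcl9 and 56.2% of the Cxcl10 UMIs of spermidine replicate 2, and 68.9% and 37.7% of those of replicate 1, while the top cell held at most 31.7% of any of the other 7 in any sample. With capped counts Cxcl10 was at 0.41 (SE 0.183) and Cxcl9 at 0.39 (SE 0.288), neither passing, and the other 7 were among 59 called genes. Under the 6-hashtag assignment 2 of the 9 were called.

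The share of tuft-like cells with a Cxcl10 UMI at 5000 UMIs was 9.55% with PBS (95% exact interval 7.444 to 12.004%) and 10.0% with spermidine (7.49 to 13.005%), at median depths of 13243 and 12165 UMIs before thinning. In thymocyte-like cells, taken as a class that should lack the gene, it was 24.0% and 12.8%, or 6 of 25 and 6 of 47 cells, at 6548 and 5414 UMIs. The 95% exact intervals there were 9.36 to 45.1% and 4.83 to 25.7%, with 12 and 34 shallower cells left out. So few cells do not fix a background level, and the tuft-like share was not shown to lie above it. In Aire-stage cells the share was 51.3% and 57.7%, at 687 and 689 CPM. Interferon-stimulated genes as a list fell in tuft-like cells, against both chemokines, with 27 of 38 lower by a median of -0.19 (mean -0.03, adjusted p = 0.0154, camera, and adjusted p = 0.789 with an estimated correlation). Over all genes 2 were called, Cxcl9 and Cxcl10, and 7 adjusted over the list alone. NF-kB targets rose in 15 of 19 genes (median 0.17, adjusted p = 0.0195, camera), cell cycle genes in 9 of 14 (median 0.29, adjusted p = 0.00899), and oxidative phosphorylation genes fell in 23 of 26 (median -0.11, adjusted p = 0.00899). With an estimated correlation these had adjusted p = 0.758, 0.758 and 0.789, with 0 called by edgeR over all genes and 0 adjusted over the list alone, and 6, 3 and 6 members at an unadjusted p under 0.05. Cluster 7, led by bitter taste receptor genes such as Tas2r105, held 91, 49, 35 and 41 of the tuft-like cells of PBS replicates 1 and 2 and spermidine replicates 1 and 2. edgeR tested 14047 genes, DESeq2 called 28, and edgeR called 498 without the low-count filter and 5 with the 6-hashtag assignment. Leaving out PBS replicate 1, PBS replicate 2, spermidine replicate 1 or spermidine replicate 2 gave 48, 38, 187 and 161 calls.

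**Figure D4:**
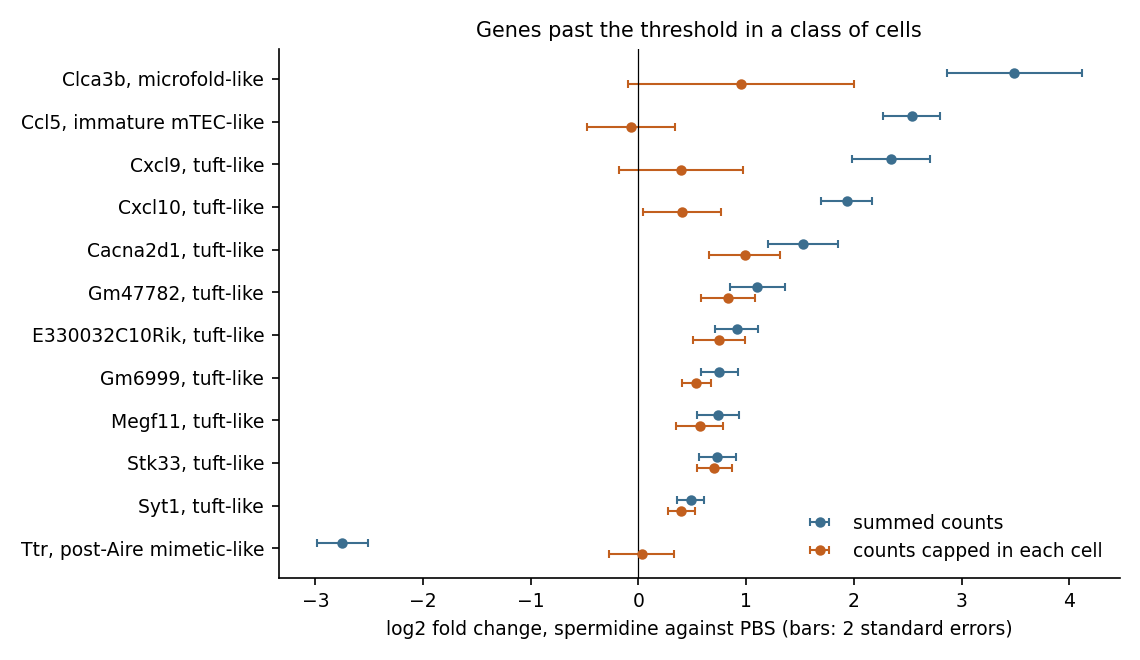
The log2 fold change of spermidine over PBS with bars of 2 SE is plotted for the called genes, for summed counts and for counts capped in each cell. Cxcl10 moved from 1.94 to 0.41 and Ttr from -2.75 to 0.03, while Syt1 moved from 0.48 to 0.40.

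The smaller mimetic classes held 1 called gene. In microfold-like cells Clca3b, a calcium-activated chloride channel regulator of the gut (GRCm38 chromosome 3, 144822623 to 144849357), rose by 3.49 (SE 0.313, adjusted p = 0.00708 in edgeR). Clca3b, also among the 10 leading genes of the neuroendocrine-like cluster, had 82.4% and 98.7% of its UMIs in the top microfold-like cell of the spermidine samples. With capped counts it was at 0.95 (adjusted p = 0.999 in edgeR). edgeR called 1 of 8849 genes there, with 396 at an unadjusted p under 0.05 and 3 by DESeq2, and 2, 58, 21 and 25 without each sample in the order above. In neuroendocrine-like cells it called 0 of 10850 (441 at an unadjusted p under 0.05, DESeq2 11), in goblet- or secretory-like cells 0 of 9431 (437, DESeq2 11) and in enterocyte- or hepatocyte-like cells 0 of 7640 (349, DESeq2 17). Without PBS replicate 1, PBS replicate 2, spermidine replicate 1 or spermidine replicate 2 these were 23, 2, 57 and 19, then 164, 172, 8 and 16, then 186, 153, 0 and 0 calls.

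Summed over all cells, which mixes levels with the makeup of classes, Aire-dependent antigens, antigen presentation, cell cycle and translation rose and interferon-stimulated genes fell as lists by camera with a preset correlation. With an estimated correlation none of the 5 held, at adjusted p = 0.678 for Aire-dependent antigens and for interferon-stimulated genes and 0.801 for the other 3. Of 47 Aire-dependent antigens 35 were higher (median 0.43, adjusted p = 1.37e-04, camera), 0 called over all genes and 18 adjusted over the list alone. Higher were also 18 of 23 antigen presentation genes (median 0.23, adjusted p = 0.00564), 27 of 28 cell cycle genes (median 0.35, adjusted p = 1.13e-05) and 24 of 25 translation genes (median 0.31, adjusted p = 1.54e-06). Lower were 26 of 40 interferon-stimulated genes (median -0.12, adjusted p = 0.0325). In these 4 lists 0 genes were called by edgeR over all genes and 3, 1, 19 and 4 adjusted over the list alone, with 8, 11, 19 and 15 members at an unadjusted p under 0.05. Beside these, thymocyte markers were higher in 10 of 10 genes (median 0.83, adjusted p = 2.80e-05) and erythroid markers in 5 of 5 (median 2.27, adjusted p = 0.00729). Both had adjusted p = 0.386 with an estimated correlation, 0 called over all genes and 7 and 4 adjusted over the list alone. The genes with the smallest p were Csn1s2a at 1.74 (SE 0.125), the binding protein Igfbp3 at 2.01, the muscle gene Ttn at 0.80, the fibrinogen gene Fgb at 2.53 and Pou4f3, with 1 and 1 counts with PBS and 78 and 47 with spermidine. These Pou4f3 counts lay in 6 and 4 cells of the spermidine samples, and the top cell held 41.0% and 93.6% of them. With capped counts Csn1s2a was at 1.01 and Fgb at 0.68. On the lower side were Krt10 at -1.07 (SE 0.06), Tmem45b at -0.82, Fxyd6 at -0.87, Klk1b26 at -0.69 and Car7 at -0.77, and all 10 had adjusted p = 0.120 in edgeR. Aire was at 315 CPM with PBS and 489 CPM with spermidine, a log2 fold change of 0.64 (adjusted p = 0.173), and Ccl21a at -0.76 (adjusted p = 0.162). edgeR called 0 of 22660 genes, with 4091 at an unadjusted p under 0.05, DESeq2 814, edgeR without the low-count filter 2991 and with capped counts 1388. Without PBS replicate 2 it called 762 and without spermidine replicate 1 11, and without thymocyte-like and myeloid-like cells 0 of 22539 with 4046 at an unadjusted p under 0.05.

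In immature mTEC-like cells, a class fitted after the data were examined, the cell cycle list fell. All 26 cell cycle genes were lower, by a median of -1.13 (adjusted p = 4.99e-15, camera, and adjusted p = 0.970 with an estimated correlation), 0 called over all genes and 8 adjusted over the list alone. Interferon-stimulated genes were lower in 33 of 39 (median -0.15, adjusted p = 0.0410, and 0.970 with an estimated correlation). The cTEC markers were lower in 6 of 6 (median -0.34, adjusted p = 0.00436, and 0.225 with an estimated correlation). In both 0 genes were called over all genes and 0 and 1 adjusted over the list alone. The chemokine Ccl5 (GRCm38 chromosome 11, 83525778 to 83530518) rose by 2.54 (SE 0.132, adjusted p = 0.00128 in edgeR), the 1 call of 10786 genes, with 581 at an unadjusted p under 0.05 and 4 by DESeq2. Ccl5, also among the 10 leading genes of Aire-stage cluster 4, had 92.4% and 92.6% of its UMIs in the top immature mTEC-like cell of the spermidine samples. With capped counts it was at -0.07. Leaving out PBS replicate 1, PBS replicate 2, spermidine replicate 1 or spermidine replicate 2 gave 7, 7, 9 and 3 calls, and the margin rule, Leiden resolution 0.5, the 6-hashtag assignment and the replicate block gave 0 each.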

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

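The tests of depth and doublets for rare genes, both tests for the shares, and the tests of free RNA and of few cells for the chemokines were chosen only after the result was seen, as were the 6-hashtag assignment and capped counts.

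Hashtags to which the labels gave no sample marked many cells. Under the 6-hashtag assignment HT6, with 22.2% of hashtag UMIs, marked 1187 kept cells with 18895979 UMIs, and HT7, with 8.66%, marked 1219 cells with 21039330 UMIs. HT6 and HT7 had 5275279 and 2057190 hashtag UMIs, against at most 13890 for each of the other 9 hashtags without a sample. Their cells held Aire at 403 and 523 CPM, against 522 and 456 CPM in cells of the spermidine hashtags HT2 and HT3 and 250 and 370 CPM in those of the PBS hashtags HT4 and HT5. The tuft cell channel gene Trpm5 was at 239 and 181 CPM, and Ccl21a at 316 and 271 CPM. Of these cells 59 and 45 were also assigned to a labelled sample with 4 hashtags and entered its comparisons. The other cells of HT6 and HT7 entered none under that assignment. Of the 4709 cells assigned with 4 hashtags, 897 were doublets with 6 hashtags, at 18.4%, 19.8%, 18.6% and 19.7% of PBS replicates 1 and 2 and spermidine replicates 1 and 2.

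In summed, uncapped counts the change of Cxcl9 and Cxcl10 differed between tuft-like and Aire-stage cells. The log2 fold change in tuft-like minus that in Aire-stage cells was 2.43 (SE 0.211) for Cxcl9 and 1.92 (SE 0.168) for Cxcl10, the 2 genes of 18962 that passed the interaction test, each with adjusted p = 0.0249 (edgeR). A broad mix of myeloid-like cells into the class was argued against. The 20 leading myeloid-like genes had a median of 0.04 (0.038, SE 0.215), against the 0.968 needed. That median over sums of the class could not show 1 or a few foreign cells, and single cells held most of the Cxcl9 UMIs. Free RNA was argued against by the design, since all 4 samples shared 1 pooled run and its free RNA would reach both groups. In the test the share of tuft-like cells with a Cxcl10 UMI was at most 13.005% with spermidine, below the 35.8% needed. That bound was set by the fold in CPM, which few cells carried, so the test adds little. The test of doublets of cells from 2 hashed samples could not decide. Under the 6-hashtag assignment Cxcl10, the lower of the pair, was at 0.87 (0.869, SE 0.427), just above the predicted bound of 2 SE (0.854). In the same assignment Cxcl9 was at 1.29 (SE 0.662), below 2 of its own SE, and neither passed (adjusted p = 0.521 and 0.544 in edgeR). Both values were smaller than in the main assignment, so such doublets stay open. Doublets within 1 sample, which share a hashtag, were not tested. A few cells with many UMIs of the genes stay open as a candidate explanation: with capped counts Cxcl9 was at 0.39 (0.394, SE 0.288), within 2 SE of 0, and Cxcl10 at 0.41 (0.405, SE 0.183), just above 2 SE. An effect of spermidine on rare tuft-like cells stays open too and was not tested apart from these.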

How the results depend on the processing

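The 6-hashtag assignment, capped counts, clusters 2 and 4 alone and all settings of immature mTEC-like cells were chosen only after the data were seen. With 2 samples per group, exact tests of shares and genes per cell cannot fall below 0.333, and in the simulation of Aire-stage cells 15% of 2-fold changes were recovered, so counts of calls there have little power. Of 294 values of gene lists under alternatives 221 were the same, 39 moved, 8 became stronger and 26 weaker; of 2528 values of named genes 2211 were the same, 125 moved, 157 became stronger, 33 weaker and 2 reversed; of 296 values of summary results 181 were the same, 106 moved, 7 became weaker and 2 reversed. The causes were not tested except where named.

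Counts of called genes are given for Aire-stage, transit-amplifying-like, post-Aire mimetic-like, all, tuft-like, microfold-like, neuroendocrine-like, goblet-like, enterocyte-like and immature mTEC-like cells in this order, where they were 0, 0, 1, 0, 9, 1, 0, 0, 0 and 1. DESeq2 called 94, 17, 29, 814, 28, 3, 11, 11, 17 and 4. Genes with 1 or more counts gave 160, 478, 709, 2991, 498, 148, 258, 261, 260 and 189. Capped counts gave 1, 7, 0, 1388, 59, 1, 0, 1, 4 and 0, and the 6-hashtag assignment 0, 0, 1, 0, 5, 1, 2, 2, 2 and 0. Equal counts can hold different genes. The main fit shared 0 genes with the 6-hashtag call in post-Aire mimetic-like cells and 0 with the capped call in microfold-like cells. Leaving out 1 sample, where the lone one was assumed to vary like the other group, gave 0 to 1, 0 to 63, 4 to 43, 0 to 762, 38 to 187, 2 to 58, 2 to 57, 8 to 172, 0 to 186 and 3 to 9. The margin rule and Leiden resolution 0.5 gave 0 in post-Aire mimetic-like and in immature cells, cells with 3000 or more UMIs gave 4 in microfold-like cells, and thinning to the lowest total gave 3 in transit-amplifying-like cells. The replicate block gave 0, 14, 1, 0, 150, 20, 2, 5, 8 and 0. Replicate numbers did not pair the samples, with correlations of same-numbered deviations of 0.025, -0.068, 0.017, -0.009 and 0.007 in Aire-stage, transit-amplifying-like, post-Aire mimetic-like, all and tuft-like cells.

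Of the gene lists in Aire-stage cells 3 passed, against 5 with the 6-hashtag assignment, 0 with it and an estimated correlation, 0 with an estimated correlation alone, 0 with fry and 0 to 3 without 1 sample. The median of the sparse genes, 0.147, was 0.168 with genes of 1 or more counts, 0.098 with the margin rule, 0.063 with the 6-hashtag assignment (with a preset or an estimated correlation), 0.046 in cluster 2 alone, -0.029 in cluster 4 alone and 0.147 with fry, none past the threshold, and -0.042 to 0.342 without 1 sample, reversed in cluster 4 and without spermidine replicate 1. Capped counts reversed Ttr in post-Aire mimetic-like cells (0.029) and Ccl5 in immature cells (-0.070), since few cells held most of their UMIs. The difference in genes per cell was -20.75 for the median over cells, 222.433 without thinning and -17.542 to 5.791 without 1 sample. That in rare genes was 2.767 and 6.139 at 3000 and 10000 UMIs, 14.603 without thinning, 2.808 with the margin rule, 2.314 in cluster 2, 0.987 in cluster 4 and 2.905 to 5.99 without 1 sample.

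Differences in shares, in percentage points, were 4.83 with the margin rule and 4.255 at Leiden resolution 0.5 for transit-amplifying-like cells and -2.01 with the 6-hashtag assignment for goblet-like cells. For enterocyte-like cells they were 0.117 with the margin rule, 0.263 with the 6-hashtag assignment and -0.405 in cells with 3000 or more UMIs. Without 1 sample these ran from -0.815 to 0.637. With the 6-hashtag assignment the differences were -0.335 for ciliated-like cells, whose groups then overlapped, and -0.487 for microfold-like cells. For muscle-like cells they were -0.308 with the margin rule, -0.54 at Leiden resolution 0.5, -0.257 with the 6-hashtag assignment and -0.52 to -0.315 without 1 sample, and for myeloid-like cells -0.062 to 0.767 without 1 sample. Leiden resolution 0.5 gave no value for all cells, goblet-like and enterocyte-like cells. The alternative with Scrublet and the test of CA repeats at promoters were not run.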

Other observations

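The tests of depth and of doublets for rare genes and both tests for the shares were chosen only after the result was seen, as were the capped counts and the genes named in the next paragraph, chosen after their values were seen.

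With the count of each gene capped in each cell, tuft-like cells had 59 called genes, 35 higher and 24 lower. The cap, at 5 or at the 99th percentile of the class, limits the weight of a single cell but does not remove it. Lower were the tuft cell cytokine Il25 at -0.49 (SE 0.085, adjusted p = 0.0166 in edgeR), the interferon-induced genes Bst2 at -0.64 and Ifi27l2a at -0.79, the cathepsin Ctsl at -0.59, Anxa2 at -0.54 and Krt19 at -0.39. Higher were Stk33 at 0.70, Syt1 at 0.40, the transcription factor Bach2 at 0.51, the prolactin receptor Prlr at 0.85 and the heat shock gene Hspa1b at 0.51. Under the 6-hashtag assignment, without capping, 3 of the 59 were called and 58 had the same direction, a count that the many cells shared by both settings raise. In transit-amplifying-like cells 7 genes were called: Kpna2 at -1.33, Cdk1 at -0.81, Ube2c at -0.87, Bub3 at -0.65 and Csmd1 at -0.57 were lower, and Naa25 at 0.75 and Cdh13 at 1.94 higher. Under the 6-hashtag assignment, without capping, 0 of the 7 were called and 6 had the same direction, with Cdh13 at -0.37. In all cells 1388 genes were called, 687 higher and 701 lower.

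Aire-stage cells of spermidine samples held more rare genes, by 4.45 per cell at equal depth. Depth was argued against as the whole cause in the main assignment, since the difference at 5000 UMIs (4.448, SE 1.57) lay above 2 SE. Under the 6-hashtag assignment, which leaves out doublets of cells from 2 hashed samples, the difference was 3.81 (3.805, SE 1.424), above 2 SE. Such doublets were a similar part of all 4 samples (18.4 to 19.8%). Leaving them out could thus hardly have removed the difference, and the test does not decide on doublets. With the margin rule the difference was 2.81, within 2 SE of 0, at 31.7 and 31.6 with PBS and 36.6 and 32.4 with spermidine. With 2 samples per group 2 SE is a loose bound, and the exact permutation test gave p = 0.333 in all these settings. A larger share of cluster 2, which held more rare genes per cell, stays open as a candidate explanation: the mean difference within clusters 2 and 4 was 1.65 (SE 0.994), within 2 SE of 0, but that within cluster 4 was 0.987 (SE 0.481), just above 2 SE, and that within cluster 2 was 2.31 (SE 1.60). An effect of spermidine within cells of each cluster stays open too.

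Aire-stage and transit-amplifying-like cells together were 31.4% ± 6.71 (SD, n = 2) of cells with PBS and 47.6% ± 0.048 (SD, n = 2) with spermidine. Under the 6-hashtag assignment, which leaves out doublets of cells from 2 hashed samples, the difference was 19.1 percentage points (19.063, SE 5.211), above 2 SE. Such doublets were a similar part of PBS replicates 1 and 2 (18.4% and 19.8%) and spermidine replicates 1 and 2 (18.6% and 19.7%). Leaving them out could thus hardly have removed the difference, and the test does not decide on doublets. The proportion in which the sorted populations were pooled stays open: it would move all post-Aire classes by 1 factor, and the tuft-like share among them differed by -0.662 (SE 0.529), or by -3.52 (SE 1.89) under the 6-hashtag assignment, both within 2 SE of 0, as were 7 of 8 post-Aire classes, or 8 of 8 in that assignment, all but the keratinocyte-like share at -1.275 (SE 0.595), or -1.10 (SE 0.900). Within the Aire-stage class the share of cluster 2 differed by 11.1 percentage points (SE 3.16), or by 10.0 (SE 1.92), and that of transit-amplifying-like cells among both classes by 4.38 (SE 1.32), or by 2.00 (SE 1.99), which pooling alone would not give if these cells came from 1 sorted population, and the labels did not say. A change of the thymus by spermidine stays open and was not tested.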
